A study of Mus musculus with 12 samples.

How the data were processed

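RNA was measured in 12 libraries of sorted EpCAM-positive cells from mouse orthotopic colon tumours, 4 mice in each of 3 groups (vehicle for 3 d, MRTX1133 for 3 d and MRTX1133 for 16 d). Per the labels' protocols, RNA was extracted with the RNeasy Plus Micro kit, 2 ng was amplified with Smart-Seq V4 and made into libraries with Nextera XT, and single-end reads of 50 bases were sequenced on a NovaSeq 6000. Smart-Seq and Nextera XT do not mark strand. Groups and replicate numbers were taken from the sample titles, which give a different mouse number for every library.

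The authors deposited a table of raw counts per gene, whole numbers without normalization per the values in the file, for 52636 Ensembl genes. They also deposited a table of log2 CPM for 16810 genes. The submitters' processing notes name GSNAP, edgeR, limma and the genome build GRCm38.p5, with no versions. The gene annotation used for counting, and how reads that match several genes were counted, are not given in the sources used here. The deposited log2 CPM values were recomputed from the counts with a prior count of 3, and 100% of values lay within 1e-06. Symbols were found for 52403 of the gene identifiers (99.56%) in the reference annotation, and genes without one held 0.0246% of counts. Gene positions are those of GENCODE M21 on GRCm38. No table column lacked a sample.

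Tests were run on the deposited counts in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 16383; 21930 genes had no count in any library. Counts were scaled by TMM, all 12 libraries were fitted in one model of 3 group means with glmQLFit (robust) on 9 residual degrees of freedom, and the 3 contrasts were tested with glmQLFTest. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a contrast. Standard errors of log2 fold changes are the fold change divided by the square root of its F statistic. CPM values use the TMM library sizes.

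Gene lists of pathways and cell types were fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes. There were 43 lists with 902 entries, of which 901 matched an identifier and 769 were tested, and 41 lists had at least 5 tested members. Each was tested with camera (limma 3.58.1, preset inter-gene correlation 0.01) on log2 CPM with a prior count of 2, adjusted over the 41 lists and 3 contrasts. Calls over the members were counted over all genes tested and adjusted over the list alone. The list test was repeated with an estimated correlation, and with fry, which asks whether a list's genes move one way and does not compare them with other genes. Differences in library measures were tested with exact two-sided permutation tests over the 70 splits of 4 against 4 libraries, adjusted over the family.

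Genes were named by a fixed rule. For each comparison with vehicle these were the 10 largest rises and the 10 largest falls among called genes with a mean log2 CPM of at least 2 and no overlap between the libraries of the 2 groups, and for 16 d against 3 d the 5 largest of each. Predicted genes, pseudogenes and features without a symbol were left out. Up to 4 members of each list with the smallest p were added as examples, and also Apc, Kras, Trp53, Smad4, Epcam, Hras, Nras, Lgr5, Mki67, Cdkn1a, Myc, Emp1, L1cam, Ly6a, Krt20, Egfr and Cd274. Lyz2 and Olfm4 values per library were singled out after they were seen.

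The test was checked on simulated counts with 200 planted genes, drawn from the real means, dispersions and library sizes. For 3 d against vehicle (16057 genes) it recovered 29.9% of 1.5-fold, 58.2% of 2-fold and 84.8% of 4-fold changes. For 16 d against vehicle (16017 genes) it recovered 37.3%, 67.2% and 83.3%, and for 16 d against 3 d (16030 genes) 38.8%, 67.2% and 80.3%. The share of false calls was 3.76%, 3.55% and 2.13%. A planted list was called in all 3 comparisons, and 0 of the 41 other lists were called by camera. The simulated genes were drawn independently of each other. This check therefore cannot show how often camera with its preset correlation calls lists of correlated genes falsely. The recovered shares hold for 200 planted genes and are not those of the real comparisons, where more calls make the adjusted threshold less strict. Totals of 19096787 to 27540051 counts per library set the counting error, and intervals on counts cover counting error only.

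Alternatives were DESeq2 (1.42.0) size factors, upper-quartile factors or library size alone, the DESeq2 Wald test, limma-voom with and without quality weights, limma-trend on the deposited log2 CPM, a fit without robust estimation, other count filters and thresholds, fits of 8 libraries, subsets of vehicle libraries, the replicate number as a block, and leaving out each library in turn. After the data were seen, a colon position score, a macrophage score (mean log2 CPM of 7 genes) and the removal of the 2 libraries lowest in colon position genes were added. For the class II list at 16 d and the goblet list between 3 d and 16 d, the mean log2 CPM of the list in each of the 12 libraries was also regressed on group, with and without the score. The 95% intervals came from the t distribution. Because both comparisons with vehicle share its 4 libraries, their likeness was set beside 20 simulations of unchanged groups and beside the 6 ways to split the vehicle libraries 2 and 2.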

Results

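RNA sequencing was performed on tumour cells from mice carrying orthotopic colon tumours grown from AKPS organoids. These are mouse small-intestinal organoids that lack Apc, Trp53 and Smad4 and carry the activating Kras G12D allele. Organoids at passage 5 were injected into the colon wall of C57BL/6N mice, and treatment began 4.5 weeks later. One group of 4 mice received vehicle for 3 d, a second group of 4 received MRTX1133 for 3 d, and the last group of 4 received MRTX1133 for 16 d. MRTX1133, a small-molecule inhibitor selective for the KRAS G12D protein, was injected intraperitoneally at 30 mg/kg in 2 doses per day. Cells carrying the epithelial surface protein EpCAM were sorted from each tumour, and each of the 12 libraries came from a different mouse. The series title asks whether KRAS G12D inhibition moves the transcriptome of metastatic cells part of the way back. No vehicle group was treated for 16 d, so both comparisons of the 16 d group, with vehicle and with 3 d of MRTX1133, also contain any change that comes with tumour age.

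Total counts per library were between 19096787 and 27540051, with means of 23670000 in vehicle, 23450000 at 3 d and 23230000 at 16 d. Exact two-sided permutation tests found no difference between these (adjusted p = 0.914 for each pair of groups). More genes were detected after treatment: 21790 ± 565 in vehicle, 22740 ± 439 at 3 d and 23240 ± 342 at 16 d (SD, n = 4). The exact permutation p of each treated group against vehicle was 0.0286, the smallest that 4 against 4 libraries can give, and 0.04 after adjustment. Mitochondrially encoded genes took 0.350 ± 0.0386% of counts in vehicle, 1.11 ± 0.163% at 3 d and 0.700 ± 0.158% at 16 d (SD, n = 4), and each pair of groups differed (exact permutation p = 0.0286, adjusted p = 0.04). The 50 most abundant genes held 13.1 ± 0.199%, 13.0 ± 0.883% and 10.8 ± 0.659% of counts in the same order, lower at 16 d than in either other group (exact permutation p = 0.0286, adjusted p = 0.04). The first principal component held 45.2% of the variance of log2 CPM, the second 14.6% and the third 10.1%. Each library came from a different mouse and was counted as a separate sample. The counts of no pair within a group agreed within sampling noise (chi-square per degree of freedom of 14.2 to 33.6).

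All groups carried the same engineered alleles, and counts per gene do not separate the mutant from the normal allele. Apc averaged 76 CPM in vehicle, 75.7 at 3 d and 84.1 at 16 d, Trp53 77.5, 70 and 67, and Smad4 65.1, 51.8 and 71.6. None of these 3 genes passed the test in any comparison (adjusted p between 0.0536 and 0.965). Epcam, the gene of the sorting marker, averaged 3350 CPM in vehicle and fell by 0.51 ± 0.08 on the log2 scale at 3 d and by 0.51 ± 0.08 at 16 d. Here and below, the value after a log2 fold change is its standard error, with 4 libraries per group, and a call means an adjusted p under 0.05 in edgeR's quasi-likelihood test.

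The first comparison asked what 3 d of KRAS G12D inhibition did to the tumour cells. Transcripts that report RAS-MAPK signalling fell (17 of 20), and so did genes of mitosis (30 of 30), of hypoxia and glycolysis (24 of 25) and of cholesterol synthesis (22 of 25). Among those that rose were 11 of 15 WNT target, 21 of 30 oxidative phosphorylation and 11 of 19 class I antigen presentation genes, together with 12 of 15 macrophage markers. Of 16383 genes tested, 3292 rose and 3348 fell, and 1981 of these 6640 genes changed at least 2-fold. Libraries of the 2 groups did not overlap for 37.5% of tested genes, against 2.86% by chance. The share of higher calls was 49.6%, but 71.4% with scaling to library size alone and 60.8% with upper-quartile factors. Those scalings moved the median log2 fold change of all genes to 0.23 and 0.14, so directions are relative to the middle of the transcriptome.

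Here and below, the largest changes are those among genes that met the rule for naming. Cryab led the 10 largest rises at 3 d. This gene of a small heat-shock protein (ENSMUSG00000032060, GRCm38 chromosome 9, 50751325 to 50756636) went from 1.93 ± 0.411 to 45.3 ± 7.04 CPM (SD, n = 4), a log2 fold change of 4.55 ± 0.21 (adjusted p = 7.39e-09). Hp, which encodes haptoglobin (ENSMUSG00000031722, chromosome 8, 109575128 to 109579172), went from 4.33 ± 1.86 to 72.9 ± 8.21 CPM, a rise of 4.06 ± 0.24. The protease inhibitor Serpinb11 rose by 4.19 ± 0.30, the L1-family adhesion gene Chl1 by 4.09 ± 0.38, the LIM homeobox factor Lhx6 by 3.97 ± 0.47 and the WNT ligand Wnt6 by 3.85 ± 0.41. Plscr2 rose by 3.79 ± 0.25, Sptssb by 3.78 ± 0.38 and the membrane protease Tmprss6 by 3.61 ± 0.41. Cd74, the class II invariant chain, rose by 3.83 ± 0.90 (adjusted p = 0.00717), but limma-voom did not call it (3.43, adjusted p = 0.083). Nor did edgeR call it with either pair of vehicle libraries alone (3.82 and 3.79) or with a macrophage score as a covariate (0.89).

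Uts2, which encodes the peptide urotensin 2 (ENSMUSG00000028963, chromosome 4, 150997097 to 151001810), fell from 42.4 ± 12.9 to 0.975 ± 0.12 CPM (SD, n = 4), a log2 fold change of -5.43 ± 0.29. The lipid droplet gene Cidea changed by -5.11 ± 0.32 and Ivl, which encodes the squamous envelope protein involucrin, by -5.06 ± 0.60. The cytokine gene Il1a (ENSMUSG00000027399, chromosome 2, 129299610 to 129309972) fell from 156 ± 38.0 to 4.96 ± 2.89 CPM, a change of -4.95 ± 0.37. The other 6 of the 10 largest falls were the tetraspanin Cd53 (-4.42 ± 0.33), Sprr2h (-4.28 ± 0.95), placental growth factor Pgf (-4.20 ± 0.31), Ly6c2 (-4.10 ± 0.42), Pbp2 (-3.85 ± 0.24) and Spry4 (-3.82 ± 0.28). Sprr2h and Ly6c2 belong to families of near-identical genes. Counts of such families (Ly6, Sprr2, Cxcl1 to Cxcl3, H2, Lyz1, Ces2a), and of overlapping and antisense genes, are uncertain because reads may be shared.

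Of the 20 members of the MAPK pathway output list, 17 fell at 3 d and none rose (17 adjusted over the list alone), with a median log2 fold change of -1.26. The camera test of this list gave adjusted p = 3.43e-10 (adjusted p = 0.193 with an estimated correlation). Spry4, an inhibitor in the feedback on RAS-MAPK signalling (ENSMUSG00000024427, chromosome 18, 38586247 to 38601415), fell from 67.3 ± 12.3 to 4.73 ± 2.01 CPM (SD, n = 4). The MAPK phosphatase Dusp6 (ENSMUSG00000019960, chromosome 10, 99263231 to 99267489) fell from 406 ± 22.6 to 131 ± 7.04 CPM, a change of -1.63 ± 0.09. Its relative Dusp4 changed by -1.65 ± 0.08 (adjusted p = 8.89e-09) and the ETS factor Etv4 by -2.06 ± 0.15. Of 21 RAS family and adaptor genes, 13 fell and 2 rose (14 and 2 adjusted over the list alone), with a median of -0.34 (adjusted p = 0.00137, and adjusted p = 0.385 with an estimated correlation). Among them Rasal1 changed by -3.84 ± 0.56, Map2k1 by -1.01 ± 0.10 and Nras by -0.55 ± 0.07, while Mras rose by 0.56 and Raf1 by 0.38. Kras itself changed by -0.50 ± 0.15 (adjusted p = 0.0135), a call that ended with scaling to library size alone (-0.32, adjusted p = 0.063), with vehicle replicates 1 and 2 alone (-0.39, adjusted p = 0.143) and with a macrophage score as a covariate (-0.61, adjusted p = 0.123). Hras was not called in any comparison (0.15, adjusted p = 0.211 at 3 d). The receptor gene Egfr changed by -2.02 ± 0.13 and its ligand Tgfa by -1.71 ± 0.14, whereas Fgfr3 rose by 3.19 ± 0.22.

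**Figure D1:**
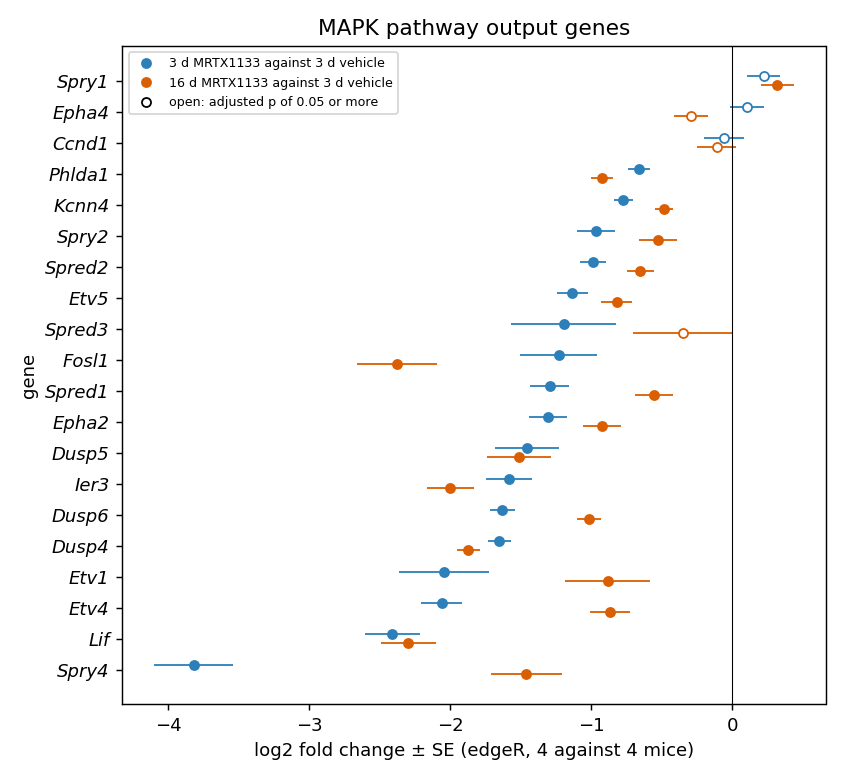
Log2 fold change of the 20 members of the MAPK pathway output list at 3 d and at 16 d of MRTX1133 against vehicle, with bars of 1 standard error (4 libraries per group) and open symbols for genes with an adjusted p of 0.05 or more. Spry4 lay at -3.82 at 3 d and at -1.46 at 16 d, whereas Dusp4 lay at -1.65 and -1.87.

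All 30 tested mitosis genes fell at 3 d (30 adjusted over the list alone), with a median of -0.95 (adjusted p = 3.08e-13, and adjusted p = 0.436 with an estimated correlation). The spindle genes Prc1 and Kif23 changed by -1.35 ± 0.14 and -1.15 ± 0.12, and the proliferation marker Mki67 by -0.64 ± 0.11. The 30 DNA replication genes had a median of 0.01 (adjusted p = 0.982), and 26 of them were not called. Myc changed by -0.42 ± 0.10 (adjusted p = 0.00296), which was not called with scaling to library size alone (-0.24, adjusted p = 0.065). The cell cycle inhibitor Cdkn1a, a p53 target in cells that have p53, changed by -1.65 ± 0.17.

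Of 25 hypoxia and glycolysis genes, 24 fell at 3 d (24 adjusted over the list alone), with a median of -1.32 (adjusted p = 1.29e-17, and adjusted p = 0.193 with an estimated correlation). The angiogenic factor Vegfa changed by -3.48 ± 0.20, and the glycolytic enzymes Pfkp and Ldha by -1.32 ± 0.08 and -1.21 ± 0.08. Of 25 cholesterol synthesis genes, 22 fell (22 adjusted over the list alone), with a median of -1.01 (adjusted p = 4.13e-14, and adjusted p = 0.264 with an estimated correlation). Pcsk9, whose protein directs the LDL receptor to degradation (ENSMUSG00000044254, chromosome 4, 106442329 to 106464329), fell from 338 ± 12.5 to 84.6 ± 7.06 CPM (SD, n = 4), a change of -2.00 ± 0.07 (adjusted p = 2.17e-09). Hmgcr, the rate-limiting enzyme of cholesterol synthesis, changed by -1.51 ± 0.09 and Insig1 by -1.49 ± 0.09. Of 30 nuclear-encoded oxidative phosphorylation genes, 21 rose and none fell (21 adjusted over the list alone), with a median of 0.32 (adjusted p = 1.39e-05, and adjusted p = 0.264 with an estimated correlation). The complex I genes Ndufa8 and Ndufa1 rose by 1.11 ± 0.08 and 0.96 ± 0.10, and the mitochondrially encoded share of counts rose with them, as given above. Of 25 genes of the integrated stress response and amino acid synthesis, 11 fell and 3 rose (12 and 4 adjusted over the list alone), with a median of -0.31 (adjusted p = 0.027, and adjusted p = 0.648 with an estimated correlation). Slc7a11 changed by -2.12 ± 0.16 and Vldlr by -2.06 ± 0.11, and the 3 that rose were Asns (0.45), Slc6a9 (0.34) and Gdf15 (0.96). With the colon position score as a covariate this list was not called (-0.27, adjusted p = 0.099).

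Of 15 WNT target genes, 11 rose and 1 fell at 3 d (11 and 1 adjusted over the list alone), with a median of 1.21 (adjusted p = 0.000194, and adjusted p = 0.193 with an estimated correlation). The WNT feedback inhibitors Nkd1, Notum and Axin2 rose by 2.44 ± 0.11, 1.44 ± 0.11 and 1.21 ± 0.10, and the transcription factor Lef1 by 1.72 ± 0.16. The member that fell was Tcf7 (-0.61). This rise was in cells that lack Apc in every group. The 17 crypt base stem cell genes went both ways, with 6 lower (7 adjusted over the list alone), 6 not called and the others higher, a median of 0.08 and adjusted p = 0.657. Ascl2 and Rnf43 rose by 1.09 ± 0.13 and 0.87 ± 0.10, Cd44 and Slc12a2 changed by -1.40 ± 0.09 and -0.85 ± 0.10, and Lgr5 was at 0.08 ± 0.15 (adjusted p = 0.712). Krt20, a marker of differentiated intestinal cells, was at 1.86 ± 0.80 (adjusted p = 0.0916).

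Of 25 genes of the metastasis-initiating and invasive front list, 15 fell and 5 rose at 3 d (15 and 6 adjusted over the list alone), with a median of -0.61 (adjusted p = 0.00531, and adjusted p = 0.509 with an estimated correlation). Emp1, a membrane protein gene that marks metastasis-initiating cells in colorectal cancer (ENSMUSG00000030208, chromosome 6, 135362545 to 135383173), fell from 4397 ± 712 to 639 ± 122 CPM (SD, n = 4), a change of -2.78 ± 0.16 (adjusted p = 4.28e-08). Flna changed by -1.37 ± 0.10 and the integrin gene Itgb4 by -1.17 ± 0.07. The 5 that rose were the adhesion gene L1cam (1.14), Itgb6 (0.51), Mmp7 (2.92), Msln (1.40) and Krt17 (1.85). The call of Itgb6 ended without vehicle replicate 3 (0.45) or 3 d replicate 2 (0.44). Of 20 fetal and regenerative epithelium genes, 7 fell and 1 rose (7 and 1 adjusted over the list alone), with a median of -0.20 (adjusted p = 0.027, and adjusted p = 0.513 with an estimated correlation). Sprr1a changed by -3.17 ± 0.18, the EGFR ligand Areg by -2.51 ± 0.18 and Ly6a by -0.97 ± 0.10, and the member that rose was Gja1 (1.30). This list was not called without 3 d replicate 4 (-0.15, adjusted p = 0.051) or with the macrophage score as a covariate (-0.12, adjusted p = 0.0746).

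Of 19 class I antigen presentation genes, 11 rose at 3 d (14 adjusted over the list alone) and none fell, with a median of 0.51 (adjusted p = 0.000676, and adjusted p = 0.509 with an estimated correlation). Psmb10 rose by 0.68 ± 0.11 and Tapbp by 0.52 ± 0.08. Of 8 class II genes, H2-Ab1 (3.21), H2-DMb1 (2.93), Cd74 and the class II transactivator Ciita (4.40 ± 0.82) rose, 7 did so adjusted over the list alone, and none fell, with a median of 3.07 (adjusted p = 0.0157, and adjusted p = 0.624 with an estimated correlation). Of these 4 calls, limma-voom did not make those of H2-Ab1 (3.16, adjusted p = 0.0973) and H2-DMb1 (3.04, adjusted p = 0.0651), nor that of Cd74, as given above. With either pair of vehicle libraries alone, H2-Ab1 (3.70 and 2.84) and H2-DMb1 (2.85 and 2.98) were not called either. With a macrophage score as a covariate none of the 4 was called, at 0.89 for Cd74, 0.92 for H2-Ab1, 1.28 for H2-DMb1 and 3.17 (adjusted p = 0.102) for Ciita. Macrophage and monocyte markers moved with them: 12 of 15 rose (12 adjusted over the list alone), with a median of 2.84 (adjusted p = 0.0122, and adjusted p = 0.509 with an estimated correlation). Apoe rose by 3.11 ± 0.62, while Mrc1 (-1.99 ± 0.39) and Cd68 (-0.84 ± 0.18) fell, and the levels were low, with Lyz2 at 0.789 to 4.65 CPM in vehicle and 4.15 to 72.9 CPM at 3 d. With a macrophage score as a covariate neither antigen presentation list was called, at a median of 0.90 (adjusted p = 0.597) for class II and 0.31 (adjusted p = 0.0657) for class I. Of 24 inflammatory cytokine and chemokine genes, 12 fell and 4 rose (14 and 4 adjusted over the list alone), with a median of -0.64 (adjusted p = 0.0286, and adjusted p = 0.70 with an estimated correlation). Csf2 changed by -3.49 ± 0.43 and the immune checkpoint ligand Cd274 by -1.42 ± 0.27, and those that rose were Il18 (1.95 ± 0.18), Ccl2 (1.85), Lcn2 (1.45) and Icam1 (0.57). This list was not called without vehicle replicate 1 (-0.62, adjusted p = 0.0578), with the macrophage score as a covariate (-0.42, adjusted p = 0.206) or with the colon position score as one (-0.55, adjusted p = 0.067). The call of Ccl2 ended without vehicle replicate 1 (1.70) or 2 (1.77) or 3 d replicate 1 (1.44) or 3 (1.59).

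In all, 14 of the 41 lists with a test were called at 3 d by camera with its preset correlation, 5 higher and 9 lower. None was called in any comparison with an estimated correlation, for which the lowest adjusted p was 0.193, while limma's fry test called 20 lists at 3 d. List members named because a count was 5 or fewer, here and below, were chosen after their values were seen. For most genes whose call ended, the text lists the libraries whose omission ended it. For the named genes the macrophage covariate ended 81 calls over the 3 comparisons and turned the sign of 1 more (Ccl2 at 3 d, no longer called). In the 2 comparisons with vehicle, vehicle replicates 1 and 2 alone ended 52 and vehicle replicates 3 and 4 alone 35. The macrophage score itself differed between groups, at -2.33 to -0.63 in vehicle and -0.31 to 2.485 at 3 d, so the fit separates it poorly from treatment. Some calls ended with a larger fold at 3 d (Kras -0.50 to -0.61, Lyz1 2.49 to 3.08) and others with a smaller one (Cd74 3.83 to 0.89). A call that ended with this covariate therefore does not by itself show macrophage RNA.

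**Figure D2:**
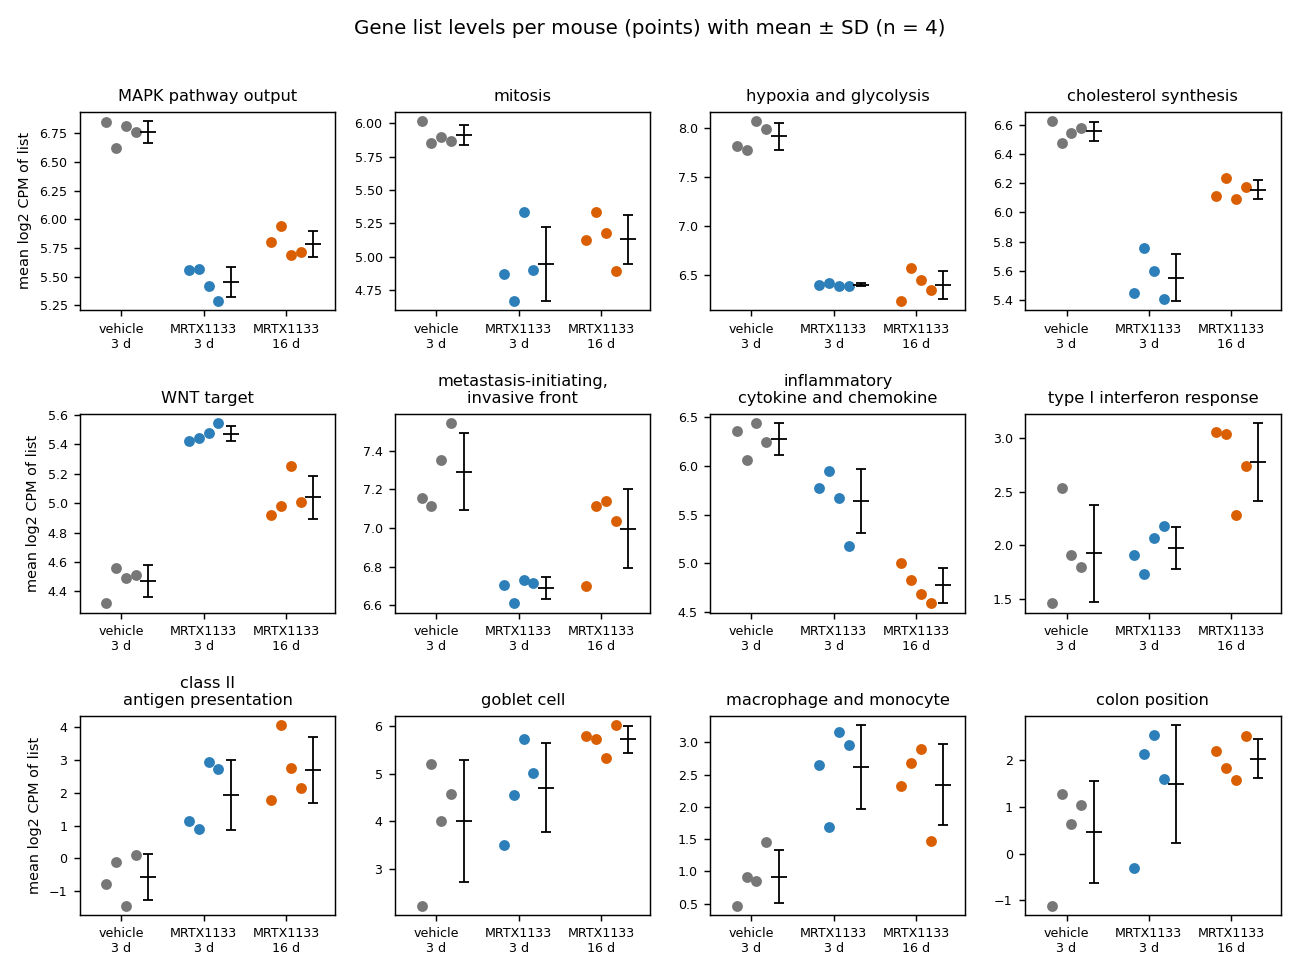
Mean log2 CPM of the tested members of 12 lists in each mouse, with a point per library and the mean and SD of each group (n = 4). The MAPK pathway output, mitosis and hypoxia and glycolysis lists have lower means in both MRTX1133 groups than in vehicle, and the class II and macrophage lists have higher means.

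The second comparison asked what the tumour cells looked like after 16 d of MRTX1133. Lower than in vehicle were 24 of 25 hypoxia and glycolysis, 16 of 20 MAPK output, 28 of 30 mitosis and 17 of 24 inflammatory cytokine and chemokine genes. Among those that rose were 8 of 19 goblet, 4 of 7 Paneth, 13 of 25 type I interferon and 7 of 8 class II genes, together with markers of macrophages (10 of 15) and endothelial cells (10 of 15). Colon position genes rose in 2 of 10 cases, close to the share of all tested genes given next. Of the 16383 genes, 3200 rose and 3303 fell, and 2082 of these 6503 changed at least 2-fold. Libraries did not overlap for 38.7% of genes, against 2.86% by chance. The share of higher calls was 49.2%, but 80.6% with scaling to library size alone and 61.9% with upper-quartile factors, which moved the median to 0.28 and 0.11.

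Among genes that met the rule for naming, Hp had the largest rise at 16 d, at 135 ± 9.37 CPM (SD, n = 4) and a log2 fold change of 4.95 ± 0.25. Cd74 rose by 4.67 ± 0.92, the glycosyltransferase B4galnt2 by 4.47 ± 0.33, Sord by 4.40 ± 0.23, the calcium-binding S100g by 4.39 ± 0.34 and Serpinb11 by 4.29 ± 0.30. The other 4 were Wfdc18 (4.26 ± 0.44), Lhx6 (4.21 ± 0.48), Cryab (4.17 ± 0.21) and angiotensinogen, Agt (4.12 ± 0.42). Among the 10 largest falls were 7 members of the inflammatory cytokine and chemokine list. Il1a changed by -4.02 ± 0.35, Cxcl2 by -3.59 ± 0.41, Cxcl1 by -3.28 ± 0.31, Csf2 by -3.26 ± 0.42, Cxcl5 by -2.97 ± 0.34 and Cxcl3 by -2.91 ± 0.43. The seventh was the NF-kB inhibitor Tnfaip3 (-3.31 ± 0.25), and the others were Serpine1 (-3.86 ± 0.48), Pgf (-3.05 ± 0.29) and the proton channel Otop3 (-2.93 ± 0.43).

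At 16 d, 16 of 20 MAPK output genes were lower than in vehicle and 1 was higher (17 and 1 adjusted over the list alone), with a median of -0.88 (adjusted p = 3.44e-08, and adjusted p = 0.193 with an estimated correlation). Dusp4 was at -1.87 ± 0.08, Ier3 at -2.00 ± 0.17, Dusp6 at -1.01 ± 0.09 and Fosl1 at -2.38 ± 0.28. The member that rose was Spry1 (0.32, adjusted p = 0.0408), whose call ended without vehicle replicate 3 (0.33) or 4 (0.22), 3 d replicate 4 (0.32), or 16 d replicate 1 (0.28) or 3 (0.27). Of the 21 RAS family and adaptor genes, 11 fell and 2 rose (11 and 2 adjusted over the list alone), with a median of -0.29 (adjusted p = 0.0327, and adjusted p = 0.509 with an estimated correlation), and neither leaving out 16 d replicate 2 (-0.31, adjusted p = 0.053) nor the macrophage score as a covariate (-0.24, adjusted p = 0.121) kept the call. Nras was at -0.61 ± 0.08, and those that rose were Sos1 (0.32) and Kras. Kras (ENSMUSG00000030265, chromosome 6, 145216699 to 145250239, minus strand) averaged 433 ± 51.5 CPM in vehicle, 305 ± 25.7 at 3 d and 948 ± 242 at 16 d (SD, n = 4), a rise of 1.13 ± 0.15 over vehicle (adjusted p = 5.18e-05). The call of Sos1 ended without vehicle replicate 1, 2 or 4 or 16 d replicate 4 (0.21 to 0.32). Egfr stood at -1.29 ± 0.13 and Fgfr3 at 2.99 ± 0.22.

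Of 30 mitosis genes, 28 were lower at 16 d than in vehicle and none was higher (30 adjusted over the list alone), with a median of -0.76 (adjusted p = 1.18e-10, and adjusted p = 0.509 with an estimated correlation). Nusap1 was at -1.17 ± 0.15 and Ccnb2 at -0.75 ± 0.09. Mki67 was at -0.36 ± 0.11 (adjusted p = 0.0175), a call that ended without 16 d replicate 4 (-0.28), with vehicle replicates 1 and 2 alone (-0.32) and under upper-quartile factors (-0.27) or scaling to library size alone (-0.10). Of 25 hypoxia and glycolysis genes, 24 fell (25 adjusted over the list alone), with a median of -1.30 (adjusted p = 2.03e-18, and adjusted p = 0.193 with an estimated correlation), among them P4ha1 (-2.04 ± 0.13), Hk2 (-1.55 ± 0.09) and Pkm (-1.30 ± 0.08). Of 25 cholesterol synthesis genes, 14 fell (14 adjusted over the list alone), with a median of -0.34 (adjusted p = 2.22e-05, and adjusted p = 0.509 with an estimated correlation), among them Srebf2 (-0.87 ± 0.08) and Ldlr (-0.85 ± 0.11). Of 25 genes of the integrated stress response and amino acid synthesis, 10 fell and 3 rose (10 and 4 adjusted over the list alone), with a median of -0.30 (adjusted p = 0.0136, and adjusted p = 0.595 with an estimated correlation). The 3 that rose were Asns (0.42), Psph (0.37) and Aldh1l2 (1.35), and with the colon position score as a covariate the list was not called (-0.20, adjusted p = 0.098). Leaving out 16 d replicate 2 ended the call of Asns (0.34), and that of Aldh1l2 ended without vehicle replicate 1, 2 or 3, 3 d replicate 1, 3 or 4, or 16 d replicate 2 or 4 (0.73 to 1.47).

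Of 24 inflammatory cytokine and chemokine genes, 17 fell and 2 rose at 16 d (17 and 2 adjusted over the list alone), with a median of -1.94 (adjusted p = 1.83e-06, and adjusted p = 0.436 with an estimated correlation). Tnf was at -2.23 ± 0.20, Nfkbia at -1.98 ± 0.18 and Cd274 at -1.90 ± 0.27, and those that rose were Il18 (1.49) and Ccl28 (2.18). The call of Ccl28 ended without any 1 of the 4 libraries at 16 d, vehicle replicate 1, 3 or 4, or 3 d replicate 2, 3 or 4 (1.78 to 2.37). Of 18 immediate early and dissociation stress genes, 13 fell and none rose (13 and 1 adjusted over the list alone), with a median of -0.58 (adjusted p = 0.000134, and adjusted p = 0.436 with an estimated correlation), among them Egr1 (-1.23 ± 0.15) and Junb (-1.10 ± 0.11). Of 25 type I interferon response genes, 13 rose and none fell (14 adjusted over the list alone), with a median of 0.83 (adjusted p = 0.00123, and adjusted p = 0.509 with an estimated correlation), among them Zbp1 (1.88 ± 0.23) and Xaf1 (1.19 ± 0.20). Of 19 class I genes, 10 rose and none fell (10 adjusted over the list alone), with a median of 0.38 (adjusted p = 0.000873, and adjusted p = 0.509 with an estimated correlation), among them Psmb9 (1.87 ± 0.37) and Psmb10 (0.96 ± 0.11). Of 8 class II genes, 7 rose (8 adjusted over the list alone), with a median of 4.03 (adjusted p = 0.00163, and adjusted p = 0.509 with an estimated correlation), among them Ciita (4.86 ± 0.82). With the macrophage score as a covariate both antigen presentation lists kept their call at 16 d, at a median of 2.18 (adjusted p = 0.0421) for class II and 0.22 (adjusted p = 0.0253) for class I. Cd74 (2.53), H2-Ab1 (2.28) and H2-DMb1 (2.70) were then not called singly.

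Markers of other cell types moved with these groups. Of 15 macrophage and monocyte genes, 10 rose and 2 fell at 16 d (10 and 2 adjusted over the list alone), with a median of 1.61 (adjusted p = 0.0443, and adjusted p = 0.624 with an estimated correlation). Csf1r rose by 1.53 ± 0.35, Lyz2 was at 3.87 to 42.7 CPM, and those that fell were Cd68 (-1.25) and Ctsb (-0.27). This call ended without 16 d replicate 2 (1.63, adjusted p = 0.079) or 3 (1.67, adjusted p = 0.0819) and with the colon position score as a covariate (1.79, adjusted p = 0.0615). Of 20 fibroblast genes, 7 rose (6 adjusted over the list alone) and none fell, with a median of 1.61 (adjusted p = 0.00794, and adjusted p = 0.767 with an estimated correlation). However, fry did not call the list (adjusted p = 0.0868), and the macrophage covariate turned the median to -0.35 (adjusted p = 0.217). Of 15 endothelial genes, 10 rose and 2 fell (11 and 2 adjusted over the list alone), with a median of 2.02 (adjusted p = 0.027, and adjusted p = 0.70 with an estimated correlation). Tie1 rose by 2.40 ± 0.48, those that fell were the VEGF receptor Flt1 (-1.47) and Ptprb (-0.72), and with the macrophage covariate the list was not called (0.41, adjusted p = 0.699). Only 4 T and NK cell genes and no B and plasma cell genes passed the count filter, so these lists had no test.

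Of 19 goblet cell genes, 8 rose and 1 fell at 16 d (8 and 1 adjusted over the list alone), with a median of 1.44 (adjusted p = 0.00341, and adjusted p = 0.648 with an estimated correlation). The goblet cell transcription factor Spdef rose by 2.02 ± 0.24, Ern2 by 1.39 ± 0.13 and Agr2 by 1.07 ± 0.15, and the member that fell was Bcas1 (-0.34). Of 7 Paneth cell genes, Itln1 (7.29 ± 0.93), Clps (5.31 ± 0.75), Habp2 (4.00) and Lyz1 (3.81) rose, 5 did so adjusted over the list alone, and none fell (adjusted p = 0.0106, and adjusted p = 0.193 with an estimated correlation), with a median of 3.82. Of 19 absorptive enterocyte genes, 7 rose and 1 fell (7 and 1 adjusted over the list alone), with a median of 1.25 (adjusted p = 0.033, and adjusted p = 0.70 with an estimated correlation). Anpep rose by 5.84 ± 0.61 and the member that fell was Ace (-1.08). The enterocyte call ended without vehicle replicate 1 (0.88, adjusted p = 0.08), 16 d replicate 2 (1.15, adjusted p = 0.0528) or 16 d replicate 4 (1.15, adjusted p = 0.0506), and with the macrophage covariate (1.52, adjusted p = 0.0657). Genes of the colon position list, which the colon expresses and the small intestine largely does not, moved with them: Hoxa10 (1.72 ± 0.34) and Hoxa13 (1.89) of 10 rose and none fell (2 adjusted over the list alone), with a median of 1.38 (adjusted p = 0.0263, and adjusted p = 0.70 with an estimated correlation). That call ended without vehicle replicate 1 (1.01, adjusted p = 0.0749) and with the macrophage covariate (1.46, adjusted p = 0.0505). With the colon position score as a covariate, the goblet list (0.10, adjusted p = 0.197) and the enterocyte list (-0.15, adjusted p = 0.812) were not called. Olfm4, a crypt base marker, had 1 count over the 4 vehicle libraries and 1520 over the 4 at 16 d, a ratio of 1550 (95% counting interval 277.5 to 61200). Among intestinal identity factors Hnf1a (2.67 ± 0.32) and Hnf4g (1.96 ± 0.28) rose and Elf3 fell (-0.94 ± 0.08), and the list of 19 went both ways (6 higher, 8 lower, median -0.16, adjusted p = 0.522).

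Of 25 metastasis-initiating and invasive front genes, 14 fell and 5 rose at 16 d (14 and 7 adjusted over the list alone), with a median of -0.73 (adjusted p = 0.0208, and adjusted p = 0.563 with an estimated correlation). Emp1 was at 1178 ± 178 CPM (SD, n = 4), a change of -1.90 ± 0.16, and the plasminogen activator Plat was at -1.69 ± 0.15. The 5 that rose were those of the 3 d comparison, with L1cam at 1.15 ± 0.13, Itgb6 at 0.58, Mmp7 at 2.28, Msln at 1.20 and Krt17 at 1.87. Of 20 fetal and regenerative epithelium genes, 13 fell and 2 rose (14 and 2 adjusted over the list alone), with a median of -0.61 (adjusted p = 0.000515, and adjusted p = 0.385 with an estimated correlation). Sprr1a was at -2.11 ± 0.17, Anxa1 at -1.18 ± 0.10 and Ly6a at -0.86 ± 0.10, and those that rose were Gja1 (1.59) and Il1rn (1.75). The call of Il1rn ended without vehicle replicate 1, 3 or 4 or 16 d replicate 2, 3 or 4 (1.47 to 1.79). The 15 WNT target genes were not called at 16 d (median 0.42, adjusted p = 0.126), with 7 higher and 3 lower (7 and 3 adjusted over the list alone). Nkd1 was still at 2.33 ± 0.11, and the 3 that fell were Lgr6 (-1.34 ± 0.09), Tcf7 (-0.39) and Dkk2 (-0.32).

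Another 3 lists of signalling targets were called lower at 16 d, with members that went both ways. Of 19 p53 target genes, 9 fell and 3 rose (10 and 3 adjusted over the list alone), with a median of -0.46 (adjusted p = 0.0157, and adjusted p = 0.434 with an estimated correlation). Cdkn1a was at -1.70 ± 0.17 and Phlda3 at -0.97 ± 0.11, in cells that lack p53, and those that rose were Sesn1 (0.65), Fas (1.04) and Xpc (0.28). Of 18 TGF-beta and BMP target genes, 10 fell and 3 rose (11 and 4 adjusted over the list alone), with a median of -0.47 (adjusted p = 0.0165, and adjusted p = 0.434 with an estimated correlation). Bmp2 and Skil were both at -1.28 ± 0.12, in cells that lack Smad4, and those that rose were Smad6 (0.58), Id3 (0.92) and Tgfb3 (0.52). Of 19 FOXO and PI3K feedback genes, 11 fell and 3 rose (12 and 3 adjusted over the list alone), with a median of -0.51 (adjusted p = 0.022, and adjusted p = 0.509 with an estimated correlation). Bcl6 was at -1.37 ± 0.12, and those that rose were Txnip (1.44 ± 0.10), Pik3ip1 (1.17) and Fbxo32 (1.48). The FOXO list was not called with the macrophage score as a covariate (-0.21, adjusted p = 0.0517). Single libraries also ended the calls of Fas (vehicle replicate 1 or 3, 16 d replicate 1, 3 or 4, 0.86 to 1.03) and Xpc (vehicle replicate 2 or 3, 16 d replicate 3 or 4, 0.22 to 0.28). In all, 23 of 41 lists were called at 16 d, 10 higher and 13 lower, and fry called 25.

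The third comparison asked how the transcriptome moved between 3 d and 16 d of MRTX1133, a difference that contains tumour age as well as the length of treatment. From their 3 d levels, 8 of 20 MAPK output and 19 of 25 cholesterol synthesis genes rose, as did Kras, while 12 of 24 inflammatory, 12 of 18 immediate early and 8 of 15 WNT target genes fell. Of the 16383 genes, 873 rose and 956 fell, and 434 of these 1829 changed at least 2-fold. Libraries did not overlap for 17.2% of genes, against 2.86% by chance. The share of higher calls was 47.7%, and 69.7% with scaling to library size alone. Without 16 d replicate 2 the number of calls was 1192, of which 1158 were among the 1829.

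Ivl rose by 4.16 ± 0.59 between 3 d and 16 d, the esterase gene Ces2a by 4.04 ± 0.58, Lgals2 by 3.94 ± 0.39, Uts2 by 3.12 ± 0.28 and Habp2 by 3.06 ± 0.81 (adjusted p = 0.0383). The call of Habp2 ended without vehicle replicate 4 or any 1 of the 8 MRTX1133 libraries (2.95 to 3.24). The 5 largest falls were Cxcl2 (-2.59 ± 0.39), the keratin Krt36 (-2.58 ± 0.32), the interferon-inducible chemokine Cxcl10 (-2.44 ± 0.36), Nfkbid (-1.99 ± 0.24) and Tnfaip3 (-1.84 ± 0.24).

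**Figure D3:**
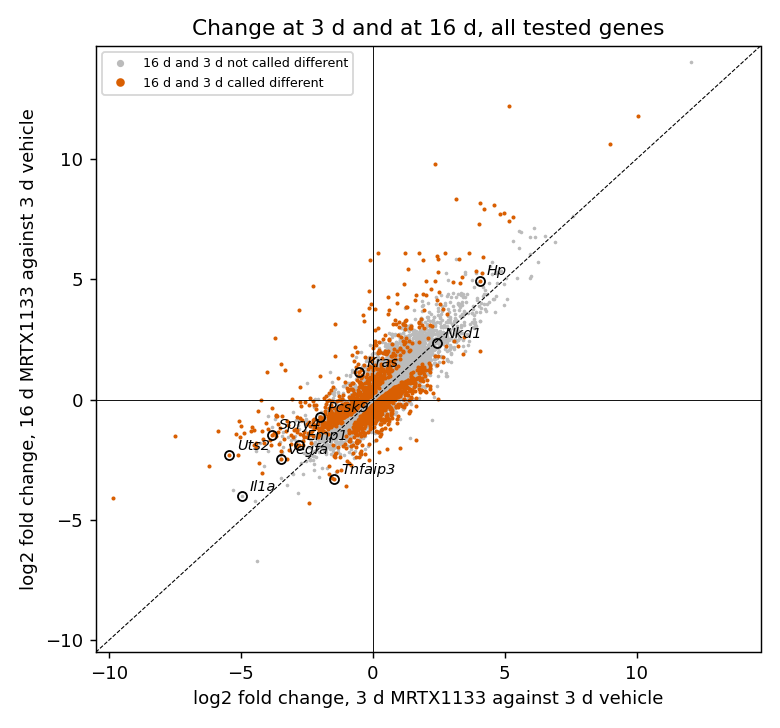
Log2 fold change against vehicle at 3 d (horizontal) and at 16 d (vertical) of all tested genes, with genes that differed between 16 d and 3 d in orange. Both axes share the 4 vehicle libraries, and named points include Hp (4.06 and 4.95), Spry4 (-3.82 and -1.46) and Kras (-0.50 and 1.13).

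Of the 20 MAPK output genes, 8 were higher at 16 d than at 3 d and 2 were lower (11 and 5 adjusted over the list alone), with a median of 0.30 (adjusted p = 0.0106, and adjusted p = 0.509 with an estimated correlation). Spry4 rose by 2.36 ± 0.27 to 24.5 ± 6.32 CPM, Etv4 by 1.19 ± 0.14 and Dusp6 by 0.62 ± 0.08 to 201 ± 25.6 CPM (SD, n = 4). The members that fell were Fosl1 (-1.15) and Phlda1 (-0.26). Leaving out 3 d replicate 1 (-1.10), 16 d replicate 3 (-1.09) or 16 d replicate 4 (-1.08) ended the call of Fosl1, and that of Phlda1 ended without vehicle replicate 1 or 4 or any 1 of the 8 MRTX1133 libraries (-0.28 to -0.22). Of 21 receptor tyrosine kinase and ligand genes, 4 rose and 2 fell (5 and 2 adjusted over the list alone), with a median of 0.25 (adjusted p = 0.0388, and adjusted p = 0.264 with an estimated correlation). Those that rose were Egfr (0.73 ± 0.13), Btc (1.14), Axl (1.68) and Fgfr4 (0.58), and those that fell were Hbegf (-1.31) and Pdgfa (-0.64). The list was not called without 3 d replicate 1 (0.17, adjusted p = 0.0867), 16 d replicate 2 (0.27, adjusted p = 0.0575) or 16 d replicate 3 (0.18, adjusted p = 0.0778). Nor was it called with the colon position score as a covariate (0.25, adjusted p = 0.0664) or without the 2 libraries lowest in colon position genes (0.17, adjusted p = 0.0747). The call of Axl ended without 3 d replicate 4 or 16 d replicate 1, 2 or 3 (1.58 to 1.73), and that of Fgfr4 without vehicle replicate 1 or 2, 3 d replicate 1, 3 or 4, or any 1 of the 4 libraries at 16 d (0.53 to 0.61). The RAS regulator Rasal1 rose by 3.51 ± 0.55.

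Kras rose by 1.64 ± 0.15 between 3 d and 16 d (adjusted p = 3.95e-05). It was accompanied by its neighbours on distal chromosome 6, a region singled out after its values were seen. Among genes with a mean log2 CPM of at least 2, the 21 genes centred on Kras lay between 140622663 and 146833529. Of these, 20 were higher at 16 d than at 3 d and 16 were called higher. Their mean log2 fold change was 0.78, or 0.74 without Kras, and the highest mean of other windows of 21 genes was 0.49. Against vehicle the window stood at 0.75 at 16 d and at -0.03 at 3 d. Over all tested genes, without this limit on expression, the 21 genes centred on Kras had a mean of 0.84, against 0.78 for the highest other window. They stood at 1.21 at 16 d and at 0.36 at 3 d against vehicle. Each of the 4 mice at 16 d lay above the 3 d mean in both windows. The values were 0.744, 0.996, 0.721 and 0.750 in the window limited by expression. Over all tested genes they were 0.874, 1.07, 0.769 and 0.819.

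**Figure D4:**
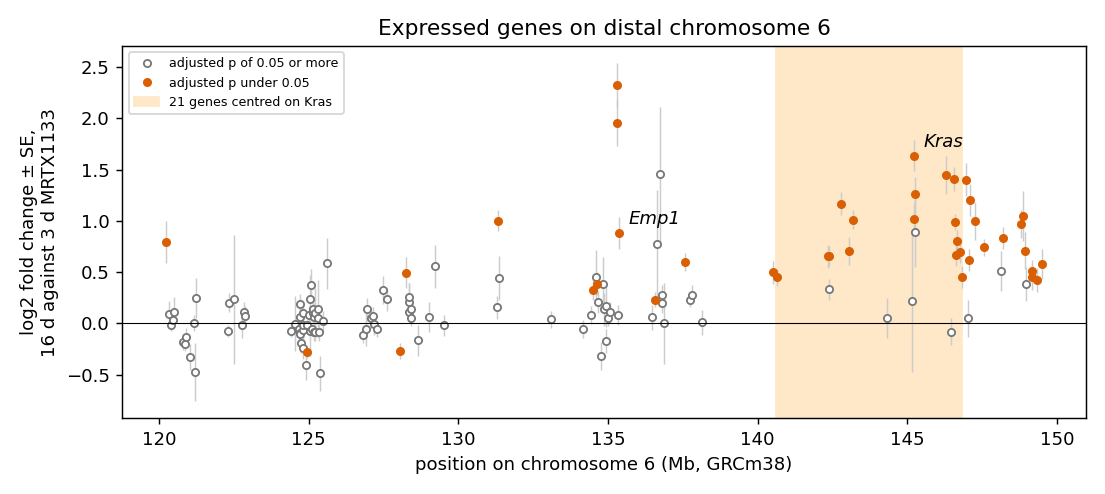
Log2 fold change between 16 d and 3 d of MRTX1133 (with 1 standard error, 4 libraries per group) of expressed genes along distal chromosome 6 (GRCm38, position in Mb). The shaded window of 21 genes contains Kras at 1.64 and has a mean of 0.78.

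Of 25 cholesterol synthesis genes, 19 rose and none fell between 3 d and 16 d (22 adjusted over the list alone), with a median of 0.60 (adjusted p = 2.33e-17, and adjusted p = 0.193 with an estimated correlation). Pcsk9 rose by 1.26 ± 0.07 to 202 ± 10.6 CPM (SD, n = 4, adjusted p = 9.18e-07 in edgeR), Insig1 by 0.89 ± 0.09 and Hmgcr by 0.82 ± 0.09. Of 30 oxidative phosphorylation genes, 9 fell and none rose (15 adjusted over the list alone), with a median of -0.22 (adjusted p = 1.33e-07, and adjusted p = 0.193 with an estimated correlation). Ndufa8 was at -0.59 ± 0.08 and Ndufb8 at -0.31 ± 0.06, and the mitochondrially encoded share of counts fell from 1.11% to 0.700%. Vegfa rose by 1.01 ± 0.18. Of 15 WNT target genes, 8 fell and none rose (9 and 1 adjusted over the list alone), with a median of -0.63 (adjusted p = 8.63e-05, and adjusted p = 0.193 with an estimated correlation), among them Dkk2 (-1.29 ± 0.09), Lgr6 (-1.16 ± 0.09), Notum (-1.06 ± 0.11) and Axin2 (-0.68 ± 0.10). For mitosis genes, a median of 0.19 was called (adjusted p = 0.00762, and adjusted p = 0.775 with an estimated correlation), but Cenpf (0.48) was the only member of 30 to pass and none passed adjusted over the list alone. That list was not called by fry (adjusted p = 0.28), nor without 3 d replicate 2 (0.09, adjusted p = 0.158) or 16 d replicate 2 (0.11, adjusted p = 0.079), its median was 0.34 without 3 d replicate 3, and the call of Cenpf ended without vehicle replicate 2, 3 or 4, 3 d replicate 1, 2 or 4, or 16 d replicate 1, 2 or 3 (0.31 to 0.52). Mki67 was at 0.27 (adjusted p = 0.136).

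Of 24 inflammatory cytokine and chemokine genes, 12 fell and none rose between 3 d and 16 d (17 and 1 adjusted over the list alone), with a median of -1.02 (adjusted p = 6.48e-08, and adjusted p = 0.385 with an estimated correlation). Csf1 was at -1.80 ± 0.21, Tnf at -1.48 ± 0.19 and Nfkbia at -1.34 ± 0.18. Of 18 immediate early and dissociation stress genes, 12 fell and none rose (12 adjusted over the list alone), with a median of -0.58 (adjusted p = 3.43e-10, and adjusted p = 0.193 with an estimated correlation), among them Atf3 (-1.19 ± 0.15). Of 25 type I interferon response genes, 7 rose and none fell (10 adjusted over the list alone), with a median of 0.81 (adjusted p = 2.86e-05, and adjusted p = 0.436 with an estimated correlation), among them Dhx58 (1.84 ± 0.33) and Oasl1 (1.35 ± 0.17). Of 19 FOXO and PI3K feedback genes, Irs1 (-0.53), Sesn3 (-0.39), Tob1 (-0.75), Bcl6 (-0.59) and Trib1 (-0.71) fell and none rose (7 adjusted over the list alone), with a median of -0.17 (adjusted p = 0.00335, and adjusted p = 0.399 with an estimated correlation), and -0.29 without 16 d replicate 1. Of the endothelial genes only Tek passed (2.15, also the 1 member adjusted over the list alone), with a median of 0.80 over 15 genes (adjusted p = 0.00292, and adjusted p = 0.56 with an estimated correlation). This median was 0.47 without 3 d replicate 2 and 1.39 without 3 d replicate 3, and the call of Tek ended without 3 d replicate 1, 2 or 4 or 16 d replicate 4 (1.87 to 2.23).

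Some goblet and Paneth cell genes rose between 3 d and 16 d. Of 19 goblet cell genes, Spdef (1.56 ± 0.23), Ern2 (1.08 ± 0.13), Agr2 (0.91 ± 0.15), Sytl2 (0.51) and Bcas1 (0.27) rose and none fell (5 adjusted over the list alone), with a median of 0.74 (adjusted p = 0.000299, and adjusted p = 0.513 with an estimated correlation), and 1.30 without 3 d replicate 3. Over libraries, the difference in the mean of the goblet list was 1.02, with a 95% interval that included 0 (-0.48 to 2.51). The call of Sytl2 ended without 16 d replicate 3 (0.48) or 4 (0.41), and that of Bcas1 without any 1 of the vehicle libraries, 3 d replicate 1, 2 or 3, or 16 d replicate 2, 3 or 4 (0.22 to 0.29). Of 7 Paneth cell genes, Itln1 (3.25 ± 0.68), Clps (2.84 ± 0.62) and Habp2 rose and Nupr1 (-1.40) fell (3 and 1 adjusted over the list alone), with a median of 2.54 (adjusted p = 0.0443, and adjusted p = 0.335 with an estimated correlation). The Paneth list was not called under DESeq2 size factors (2.55, adjusted p = 0.063) or without vehicle replicate 4, 3 d replicate 1, 2 or 4, or 16 d replicate 1 or 2 (1.77 to 2.65), and Itln1 stood at 2.11 without 16 d replicate 4. Olfm4 had 8 counts over the 4 libraries at 3 d, so the ratio of 16 d to 3 d was 191.8 (95% counting interval 97.09 to 445.1). Hnf1a rose by 2.19 ± 0.31, Hnf4g by 1.76 ± 0.27, Anpep by 3.38 ± 0.50 and the macrophage mannose receptor Mrc1 by 2.97 ± 0.40. The macrophage and monocyte list was not called in this comparison, and its member Ctsb fell (-0.35). Of 18 gastric and squamous lineage genes, Anxa10 (6.26 ± 0.71), Muc5ac (5.17), Ivl, Gkn1 (2.32) and Tff1 (1.69 ± 0.20) rose, and Krt13 (-1.43) and Krt14 (-0.998) fell (6 and 2 adjusted over the list alone). Their median was 0.35 (adjusted p = 0.0138, and adjusted p = 0.509 with an estimated correlation), 1.15 without 3 d replicate 2, and not called with the macrophage score as a covariate (0.36, adjusted p = 0.0563). Single libraries ended the calls of Muc5ac (3 d replicate 1, 3 or 4, 16 d replicate 4, 3.59 to 5.23), Gkn1 (3 d replicate 3 or 4, 16 d replicate 1, 2 or 4, 2.03 to 2.46), Krt13 (3 d replicate 2 or 3, 16 d replicate 1, 2 or 4, -1.49 to -1.14) and Krt14 (16 d replicate 2, -0.92).

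Of the 25 metastasis-initiating and invasive front genes, 7 rose and 3 fell between 3 d and 16 d (8 and 3 adjusted over the list alone), with a median of 0.26 (adjusted p = 0.0487, and adjusted p = 0.648 with an estimated correlation). Emp1 rose by 0.88 ± 0.15, Itga2 by 0.96 ± 0.13 and Flna by 0.64 ± 0.10, and the 3 that fell were Plat (-1.08 ± 0.15), Cldn4 (-1.54) and Plau (-1.11). The list call was lost with fry (adjusted p = 0.0541), with DESeq2 size factors (0.28, adjusted p = 0.0663) with either covariate (0.25, adjusted p = 0.0794 and 0.30, adjusted p = 0.0516) and without the 2 libraries lowest in colon position genes (0.25, adjusted p = 0.0697). It was also lost without vehicle replicate 1, 3 or 4, any 1 of 3 d replicates 1, 3 and 4, or 16 d replicate 2 or 3 (0.20 to 0.26). The call of Plau ended without vehicle replicate 4, 3 d replicate 1 or 2, or any 1 of the 4 libraries at 16 d (-1.16 to -0.68). Phlda3 was at -0.87 ± 0.11, and the pro-apoptotic genes Bcl2l11 and Pmaip1 were at -0.88 ± 0.10 and -0.63 ± 0.11. In all, 15 of 41 lists were called between 16 d and 3 d, 10 higher and 5 lower, and fry called 17.

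**Figure D5:**
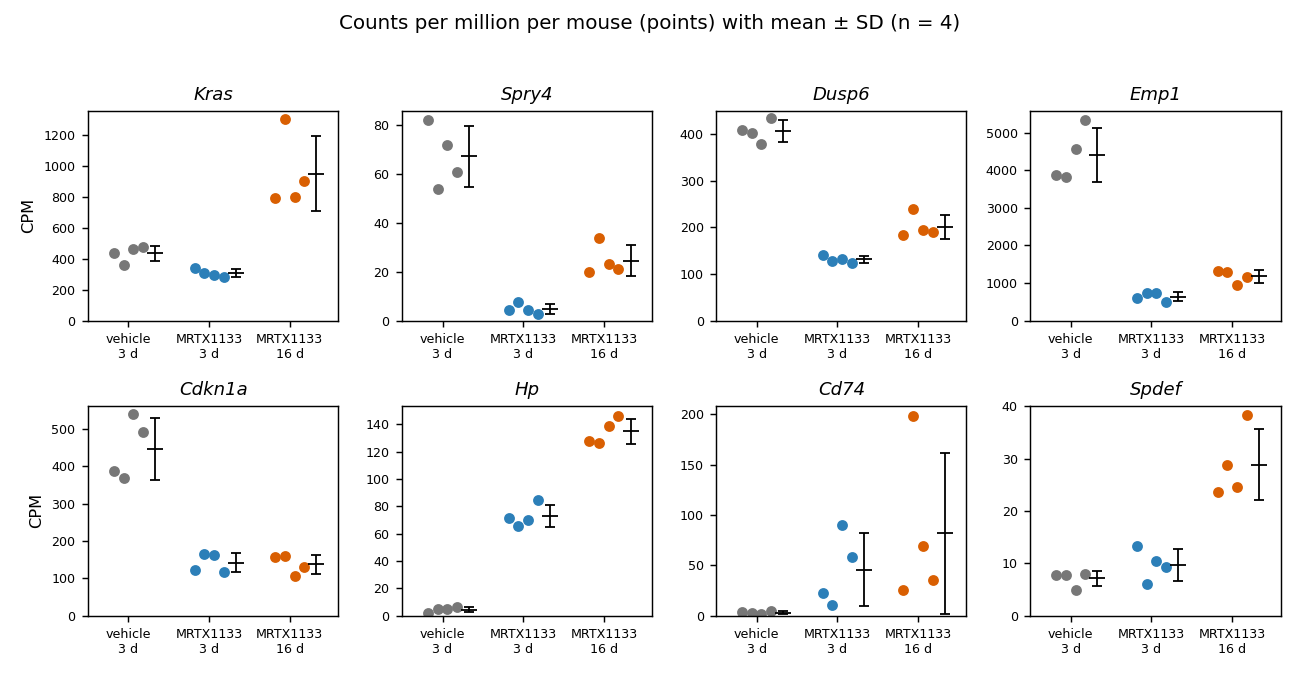
CPM of 8 genes in each of the 12 mice, with the mean of each group (n = 4). Kras lies above vehicle in every mouse at 16 d, and Spry4, Dusp6 and Emp1 have their lowest mean at 3 d and a mean between the 3 d and vehicle levels at 16 d.

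The changes from vehicle at 3 d and 16 d resembled each other. Across genes, which are not independent replicates, the log2 fold changes against vehicle correlated with r = 0.828 (Spearman's rho 0.827). Unchanged groups were simulated 20 times from the vehicle means, with all 12 libraries drawn anew and the simulated vehicle libraries shared. They gave r = 0.508, because the 2 comparisons share controls, but a covariance of 0.0654 against 0.713 observed. Genes were drawn independently, so differences that run through many genes of a real vehicle library are not in this reference. When the vehicle libraries were split 2 and 2 so that none was shared, the 6 ways gave r between 0.613 and 0.702 and a covariance between 0.675 and 0.744. Both comparisons called 2169 genes higher, against 643 for independent lists, and 2468 lower, against 675. The simulated groups, which had almost no calls (0.05 higher and 0 lower in both), give no reference for this overlap. Opposite calls were made for 43 genes. With unshared controls 1255 to 1355 genes were called higher in both and 1699 to 1780 lower in both. Of the 3292 genes higher at 3 d, 65.9% were also called higher at 16 d, and 504 (15.3%) were lower at 16 d than at 3 d while 101 were higher still. Of the 3348 genes lower at 3 d, 73.7% were also called lower at 16 d, 533 (15.9%) were higher at 16 d than at 3 d and 124 were lower still. These genes were chosen on the 3 d libraries and then compared with the same libraries, which favours a move back. The excess of moves back therefore does not measure a reversal.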

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

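The tests of a regional gain, of chance clustering and of gene length and GC among the more highly expressed genes near Kras, of macrophages for the class II genes, and of host colon epithelium for the goblet genes between 3 d and 16 d, were chosen after those results were seen, and so were the 2 covariates.

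In each comparison 1 of the 35 splits of the 8 libraries, the real one, gave as many calls. The real counts were 6640, 6503 and 1829, and the highest of the other splits was 0 in edgeR's test, with at most 2922, 2979 and 2931 genes at an unadjusted p under 0.05. Each real split was thus the only 1 of 35 to reach its count, and a share below 1 of 35 was not possible. The other splits mix the groups, so any real difference adds to their spread. Their 0 calls therefore do not show what unchanged groups would give, and chance is not excluded by this count alone.

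Kras and its neighbours on distal chromosome 6 were higher at 16 d than at 3 d, with a mean log2 change of 0.844 over the 21 tested genes centred on Kras. Chance clustering is not excluded on all tested genes, since 3.1% of 1000 shuffles of gene positions held a window at least that high (highest 1.12) and the highest other real window was 0.784, and with a length and GC trend removed (0.768) nothing is decided; among genes with a mean log2 CPM of at least 2, however, the window's 0.783 lay above every shuffle (highest 0.508) and stayed at 0.711 after the trend was removed (highest shuffle 0.519), which argues against both. The median change of 73 markers of other cell types was 0.294 (95% bootstrap interval -0.02 to 0.565), with an upper limit below the window mean. That bootstrap resampled markers and not mice, so its interval holds no spread between mice. Among these cell types only the endothelial list was called between 3 d and 16 d, with a median of 0.80. The pooled median therefore does not decide on RNA from other cell types. Of the window genes not called at 3 d, 92.9% (13 of 14) were higher at 16 d than in vehicle, which nearly follows from a window singled out for its rise after 3 d and decides nothing. A gain of the segment that carries Kras, regional regulation, RNA from other cell types and tumour age cannot be told apart. The counts hold no measure of DNA copy number, do not separate alleles and include no vehicle group at 16 d. A gain therefore remains an untested hypothesis.

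The class II list was higher in both MRTX1133 groups, and so was that of macrophage markers. Host macrophages carried through the EpCAM sort, which should remove them, may therefore account for the class II genes. The abundant macrophage gene Lyz2 was at most 72.9 CPM at 3 d and 42.7 CPM at 16 d. Class II genes were low too, with a mean log2 CPM of at most 4.055 in any library, so low Lyz2 does not speak against macrophages. Over the 12 libraries, with group means removed, the class II score followed a score of 7 macrophage genes with r = 0.651 (95% interval 0.037 to 0.908, permutation p = 0.0516) and Spearman's rho = 0.685 (permutation p = 0.0334), and r was 0.584 without the 2 libraries farthest from the median. With that score as a covariate camera did not call the list at 3 d (0.90, adjusted p = 0.597), but at 16 d it kept its call (2.18, adjusted p = 0.0421). The difference in the list mean over libraries at 16 d was then 1.88 (95% interval 0.09 to 3.66). The score includes genes with few counts, such as Aif1 at 0 to 1.18 CPM, and error in it leaves part of any macrophage effect uncorrected. The rise that remained therefore cannot exclude macrophages as the whole cause at 16 d. Among single libraries, 16 d replicate 4 had a macrophage score of -0.78, within the vehicle range of -2.33 to -0.63. Its class II score was 2.15, above the vehicle range of -1.44 to 0.10. In 3 d replicate 2 the macrophage score was -0.31, above the vehicle range of that score, with Lyz2 at 4.15 CPM and a class II score of 0.91. These 2 of 8 libraries exclude nothing by themselves. Expression in the tumour cells and macrophage RNA cannot be told apart at 3 d or at 16 d, because the interval of r includes both weak and strong relations. Other host cells and tumour age also stay open at 16 d.

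The goblet cell list was higher at 16 d than in vehicle, with a median of 1.44, together with genes of colon position, and Agr2, its most abundant member, went from 317 to 666 CPM. Host colon epithelium carries EpCAM and would pass the sort, and with the colon position score as a covariate the median was 0.101 (adjusted p = 0.197), which is consistent with RNA from host goblet cells for much of the list. Between 3 d and 16 d, however, camera called the list higher (0.74) while colon position genes were not called (0.23, adjusted p = 0.2355). With the covariate the list kept its camera call at the preset correlation (0.521, adjusted p = 0.000667). This does not decide against host colon RNA for that part, because camera with an estimated correlation did not call the list even without the covariate (adjusted p = 0.513). Over libraries, the difference in the list mean was 1.02 without the covariate (95% interval -0.48 to 2.51). With the covariate it was 0.55 (95% interval -0.10 to 1.19). Both intervals include 0, so over mice neither the rise nor its source is decided. At 16 d against vehicle the call ended because the fold fell, and 5 of 19 members were still higher and 0 lower by edgeR, namely Spdef (2.19), Ern2 (1.20), Agr2 (0.85), Creb3l1 (0.60) and Sytl2 (0.53), though the call of Creb3l1 without the covariate (1.87) ended without vehicle replicate 1 (1.58) or 3 (1.76) or 16 d replicate 4 (1.61). Secretory differentiation of tumour cells stays open for these 5 genes and for the part after 3 d, as does tumour age, and no test here separates host from tumour RNA.

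A gene or list was also singled out where 1 library of a group lay far from its other 3 by Dixon's criterion, which chance meets in about 1 in 20 groups. This was so in 40 of 603 groups for genes (6.63%), in 5 of 123 for lists (4.07%) and in 0 of 21 for library measures. Of these 45 values 12 were in 16 d replicate 2. For lists the mean log2 CPM was 1.98 for mesenchymal transition regulators and 2.72 for neutrophil markers in 3 d replicate 2, 1.47 for absorptive enterocyte and 4.52 for fatty acid oxidation and PPAR target genes in 3 d replicate 1, and 0.64 for enteroendocrine markers in 16 d replicate 3. For genes the values are CPM. In vehicle replicate 1 these were Lgals2 (38.6), Habp2 (23.8), Olfm4 (0.0493) and Hbegf (608). In vehicle replicate 2 these were Tmprss6 (0.824), Pbp2 (12.4), B4galnt2 (2.52), Plat (1860), Slc7a11 (258) and Ctsb (627). In vehicle replicate 3 these were Ndufa8 (132) and Spdef (4.94). In vehicle replicate 4 these were Ivl (45.2), Dusp4 (668) and Dkk2 (199). In 3 d replicate 1 these were P4ha1 (53.9), Olfm4 (0.329), Csf1r (4.81) and Bmp2 (87.9). In 3 d replicate 2 these were Pbp2 (0.952) and Itga2 (55.9). In 3 d replicate 3 this was Sesn3 (82.4). In 16 d replicate 1 these were Hras (80.6), Plscr2 (13.2) and Tff1 (432). In 16 d replicate 2 these were Cidea (8.48), Cd53 (49.2), Habp2 (138), Fosl1 (67.0), Kif23 (71.4), Psmb9 (18.96), Slc7a11 (119), Bcl6 (58.6), Btc (87.0), H2-Ab1 (21.7), Asns (235) and Psph (31.9). In 16 d replicate 4 these were Itln1 (128), Muc5ac (5.01) and Tek (6.34).

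Values at 16 d differed from those at 3 d of MRTX1133, a difference that contains tumour age, for 104 of the 201 named genes, some of them named because of this difference, and for 15 lists, against 11.2% of all 16383 tested genes (1829). Medians of the lists were Paneth cell (2.54), type I interferon response (0.81), endothelial cell (0.80), goblet cell (0.74), cholesterol synthesis (0.60), gastric and squamous lineage (0.35), MAPK pathway output (0.30), metastasis-initiating and invasive front (0.26), receptor tyrosine kinases and ligands (0.25), mitosis (0.19), FOXO and PI3K feedback (-0.17), oxidative phosphorylation (-0.22), immediate early and dissociation stress (-0.58), WNT target (-0.63) and inflammatory cytokine and chemokine (-1.02). Genes with higher values at 16 d were Olfm4 (7.41), Anxa10 (6.26), Muc5ac (5.17), Ivl (4.16), Ces2a (4.04), Lgals2 (3.94), Rasal1 (3.51), Anpep (3.38), Itln1 (3.25), Uts2 (3.12), Habp2 (3.06), Mrc1 (2.97), Clps (2.84), Cidea (2.83), Sord (2.47), Cd53 (2.44), Spry4 (2.36), Gkn1 (2.32), Hnf1a (2.19), Tek (2.15), Pbp2 (1.96), B4galnt2 (1.95), Dhx58 (1.84), Hnf4g (1.76), Agt (1.70), Tff1 (1.69), Axl (1.68), Kras (1.64), Spdef (1.56), Oasl1 (1.35), Pcsk9 (1.26), Etv4 (1.19), Pgf (1.14), Btc (1.14), Ern2 (1.08), Sprr1a (1.05), Vegfa (1.01), Itga2 (0.96), Areg (0.94), Agr2 (0.91), Slc12a2 (0.90), Insig1 (0.89), Hp (0.89), Emp1 (0.88), Hmgcr (0.82), Egfr (0.73), Ldlr (0.69), Flna (0.64), Dusp6 (0.62), Sos1 (0.60), Fgfr4 (0.58), Vldlr (0.52), Sytl2 (0.51), Cenpf (0.48), Bcas1 (0.27) and Itgb4 (0.26). Genes with lower values at 16 d were Cxcl2 (-2.59), Krt36 (-2.58), Cxcl10 (-2.44), Nfkbid (-1.99), Tnfaip3 (-1.84), Csf1 (-1.80), Cxcl1 (-1.73), Cxcl3 (-1.71), Cxcl5 (-1.63), Gdf15 (-1.62), Cldn4 (-1.54), Tnf (-1.48), Krt13 (-1.43), Nupr1 (-1.40), Lcn2 (-1.39), Nfkbia (-1.34), Hbegf (-1.31), Dkk2 (-1.29), Atf3 (-1.19), Lgr6 (-1.16), Fosl1 (-1.15), Plau (-1.11), Plat (-1.08), Notum (-1.06), Krt14 (-0.998), Bcl2l11 (-0.88), Phlda3 (-0.87), Lef1 (-0.81), Anxa1 (-0.75), Tob1 (-0.75), Trib1 (-0.71), Axin2 (-0.68), Bmp2 (-0.66), Skil (-0.65), Pdgfa (-0.64), Elf3 (-0.63), Pmaip1 (-0.63), Junb (-0.60), Bcl6 (-0.59), Ndufa8 (-0.59), Irs1 (-0.53), Icam1 (-0.53), Slc6a9 (-0.41), Sesn3 (-0.39), Ctsb (-0.35), Raf1 (-0.32), Ndufb8 (-0.31) and Phlda1 (-0.26). Among named genes, the calls of 20 of these 104 ended when a library was left out, against 16 of 177 at 16 d and 9 of 154 at 3 d against vehicle.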

How the results depend on the processing

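The covariates (colon position and macrophage score) and the removal of the 2 libraries lowest in colon position genes were chosen after seeing the data, and all other alternatives were planned. Across the other settings that stayed within 1.5 times, genes changed numbered 4547 to 7391 at 3 d and 5134 to 7808 at 16 d against vehicle, and 1428 to 2403 between 16 d and 3 d. Leaving out 1 library gave 5853 to 6797 (lowest without 3 d replicate 3), 5556 to 6736 (16 d replicate 3) and 1192 to 2001 (16 d replicate 2) genes, and 13 to 19, 20 to 24 and 11 to 17 lists. A 2-fold minimum left 1981, 2082 and 434 genes by construction, and an adjusted p under 0.01 left 4217 at 16 d and 797 between 16 d and 3 d. Vehicle replicates 1 and 2 alone gave 4156 genes at 16 d (3966 shared with the full fit). The macrophage covariate gave 2995 genes at 3 d (2882 shared) and 3508 at 16 d (3388 shared), and the cause was not tested. It also reversed the fibroblast list at 16 d (-0.35) and Ccl2 at 3 d (-0.60), neither of them called there. The colon position covariate gave 5756, 4543 and 1728 genes, and fits without the 2 libraries 5497, 5799 and 1240. Camera with an estimated correlation called 0, 0 and 0 lists, against 14, 23 and 15 with the preset one and 20, 25 and 17 with fry. Genes called at both times numbered 4637, and 3063, 3084, 2982, 3089, 3029 and 3015 with the vehicle libraries split, when fewer libraries entered each fit. The share of the 500 most abundant genes differed by -2.46 points at 3 d (adjusted p = 0.04 in an exact permutation test), against -0.188 for the 50 most abundant.

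Replicate numbers belong to different mice. Their deviations correlated between -0.29 and 0.59 (mean 0.0447, other pairs -0.0119), and 2 of 12 libraries correlated best with their own number. The fit with a replicate block called 6180, 6133 and 1428 genes and 15, 24 and 15 lists. On simulated counts at this depth and spread, 29.9% of 1.5-fold changes were recovered at 3 d. Depth was not varied.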

Other observations

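The Kras neighbourhood, class II and goblet results are weighed above with the tests named there, and no test in this part was chosen after its result was seen.

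Several gene lists were not called by camera at either time, which does not show that their genes were unchanged. Of 30 MYC target and ribosome biogenesis genes, 27 were not called at 3 d and 28 at 16 d, with medians of -0.03 and -0.03 (camera adjusted p = 0.617 at both times). The 30 DNA replication genes had an adjusted p of 0.628 at 16 d, and 28 were not called, whereas mitosis genes fell. Of 20 YAP and TEAD target genes, 10 were not called at 3 d, and the median was 0.16 (adjusted p = 0.522). Of 19 unfolded protein response genes, 8 were not called at 3 d and 11 at 16 d, with adjusted p = 0.847 and 0.617. Of 16 BCL2 family genes, 7 were not called at 3 d and 8 at 16 d (adjusted p = 0.559 and 0.856). Colonocyte markers had medians of 1.31 at 3 d and 1.54 at 16 d, which failed the adjusted test (adjusted p = 0.246 and 0.0853), with 10 and 12 of 14 genes not called.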
